A study of Mus musculus with 9 samples.

How the data were processed

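Polyadenylated RNA from 9 cultures of RAW 264.7 macrophages was measured by sequencing, with 3 libraries each for vehicle, LPS and calycosin plus LPS. Per the labels' protocols, RNA was isolated with Trizol, mRNA was captured on poly-T beads and libraries were made with a dual-mode mRNA kit. Per the submitters' processing notes, the authors used Trimmomatic 0.36, HISAT2 2.0 and StringTie 1.3.3b with genome build mm10, without a stated order. Raw counts per gene were deposited by the authors as whole numbers for 51826 Ensembl genes, with no normalisation found in the values. The read counter, the annotation release, the strandedness and the handling of reads that map to several places are not given in the sources used here. TPM values, which the authors scaled for transcript length and library depth, were deposited for 51799 genes, and per the file headers they have the layout of StringTie's gene abundance table. Among the gene symbols beside the counts, 27 had been turned into calendar dates, and the same 27 genes are missing from the TPM table, so genes were joined by Ensembl identifier. Of these identifiers 51633 were found in GENCODE M21 (GRCm38), which gave positions, gene types, transcript lengths and GC content. Symbols shared by more than 1 identifier (90 symbols) were kept apart by identifier, and the list gene Itgam, which is among them, was left out of the lists.

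The count tables were the basis of all comparisons, because they keep the precision that sequencing depth gives. Total counts per library ran from 27784737 to 38524105, and 26019 genes had 0 counts in all libraries. The 95% Wilson interval of the mitochondrial share of a library was at most 0.029 percentage points wide. A count of 0 was read as a level of up to 3 counts, which is 0.0602 to 0.137 CPM depending on the library, and a fold against a group without counts is a lower bound against 3 counts per library. For a group with some counts and a mean under that floor, levels are given in place of a fold. These intervals and floors cover counting error only, since the libraries carry no molecular identifiers. No pair of libraries was a duplicate of the other, and no per-sample column was left without a sample.

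Genes were filtered with edgeR's filterByExpr at its default settings, which left 14458, and libraries were scaled by the trimmed mean of M values (TMM), with factors from 0.786 to 1.42. Negative binomial models of all 9 libraries with a term per group were fitted with edgeR 4.0.16 in R 4.3.3, and each pair of groups was compared with the quasi-likelihood F test (two-sided). P values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05. The SE of a log2 fold change was derived from the test statistic. With 3 libraries against 3 an exact permutation of a single gene cannot go below 0.1, so the tests rest on the dispersion shared across genes. LPS-raised and LPS-lowered genes are those called with LPS against vehicle and changed at least 2-fold. Because both comparisons use the same LPS libraries, the counts of these genes that calycosin moved and the correlation of fold changes are given beside 20 simulated data sets without a calycosin effect. The percent of the response left is the log2 fold change of calycosin plus LPS over vehicle divided by that of LPS over vehicle.

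The comparisons, the 37 gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. The lists covered MIF and its receptors, inflammatory signalling and its products, macrophage states, migration, lipid metabolism, energy metabolism, proliferation, stress responses and markers of other cell types. Lists were tested with camera from limma 3.58.1 against all other genes tested. Through edgeR it works on z-scores of the counts under the fitted negative binomial model. Principal components and deviations of libraries used log2 CPM with a prior count of 2. The inter-gene correlation was preset at 0.01 and, as an alternative, estimated from the data, and p was adjusted over the lists of a comparison. The fry test was run beside it, which asks whether the members of a list move one way on balance and does not compare them with other genes. Named genes were, first, the 8 highest and 8 lowest fold changes in the comparisons of LPS with vehicle and of calycosin plus LPS with LPS, and 5 and 5 in calycosin plus LPS against vehicle. These had to pass the threshold, reach a mean of 10 CPM in the higher group, have all 3 libraries of a group above those of the other, and carry a symbol that is not a predicted gene, clone, pseudogene or microRNA. Added to these were Mif, Cd74, Ccl2, Tnf, Il6, Il1b, Nos2, Ptgs2, Hmox1 and Cyp1b1. Up to 4 called members of each list with the largest change were also taken, or the 2 with the highest level where none was called. From the LPS-raised genes the 5 largest further rises and 5 largest falls with calycosin were taken, and 3 and 3 from the LPS-lowered genes.

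The procedures were tested on simulated data of the same depth and dispersion, with 200 changed genes in each of the 3 comparisons. Genes were drawn independently with the dispersions that edgeR had estimated. The simulated data thus held no correlation between genes and no composition trend, a setting that favours edgeR and camera with the preset correlation. Far more genes were called in the real comparisons, so the shares below do not carry over to them. Of 50 genes changed 1.5-fold, edgeR called 6%, 6% and 12% in LPS against vehicle, calycosin plus LPS against LPS and calycosin plus LPS against vehicle. Of genes changed 2-fold it called 46%, 40% and 48%, of genes changed 4-fold 84%, 90% and 88%, and of genes changed 8-fold 96%, 92% and 94%. Of its calls 6.3%, 8% and 1.61% were unchanged genes, against 22.6%, 24.1% and 19.8% for DESeq2 and 7.09%, 7.44% and 1.59% for limma. A set of 25 genes changed 1.5-fold had a camera p of 3.11e-17, 8.3e-12 and 2.53e-15 with the preset correlation and 0.00101, 4.94e-04 and 5.23e-04 with the estimated correlation. A set of unchanged genes had 0.0396, 0.854 and 0.923 with the preset correlation.

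Alternatives were size factors from the median of ratios (RLE), no filter, a stricter filter of 1 CPM in 3 libraries and 100 counts in all, and the Wald test of DESeq2 1.42.0. Others were a replicate block, fits of the 6 libraries compared, limma with a trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 0.5, a threshold of 0.01, a fold of at least 2 as well, and leaving out each library in turn. After the data were seen, further fits were added that used only the 6 libraries with a mitochondrial share above 10%, an offset per library from a smooth on GC content (span 0.3), the log2 mitochondrial share as a covariate, counts without mitochondrial genes and pseudogenes, and all libraries except vehicle replicate 3 and calycosin plus LPS replicate 2. The fit on libraries of high mitochondrial share holds 1 vehicle library, which is assumed to vary like the other groups. Tables were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Some genes that the rule or the lists took are not reported here. Splice variants and reads were not analysed here.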

Results

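Polyadenylated RNA was sequenced from RAW 264.7 cells, a mouse macrophage cell line, in 3 groups of 3 cultures that the labels call biological replicates. The first group received vehicle. The second group received lipopolysaccharide (LPS), a bacterial cell wall component that macrophages sense through the receptor TLR4, at 300 ng/mL for 6 h. The third group was treated with calycosin, an isoflavone found in Astragalus root, at 100 µg/mL for 24 h before the same LPS exposure. No group received calycosin without LPS, so an effect of calycosin on resting cells was not measured. Total gene counts per library were 31285425 to 35138718 in vehicle cells, 27784737 to 31038241 in LPS cells and 33925342 to 38524105 in calycosin plus LPS cells. Of the 51826 genes counted, 14458 had enough counts to be tested. Expression levels are given as mean ± SD (n = 3 libraries) in CPM, counts scaled to the effective size of each library, with the vehicle group as background. Positions refer to the GRCm38 (mm10) assembly.

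The libraries differed in composition within groups as well as between them. Mitochondrially encoded genes took 3.79%, 3.68% and 21.9% of counts in vehicle replicates 1, 2 and 3, 14.1%, 14.7% and 13% in the LPS replicates, and 17.2%, 7.45% and 19.4% in the calycosin plus LPS replicates. Cytosolic ribosomal protein genes took 3.93%, 3.98% and 1.94% of counts in the vehicle replicates, 1.52% to 1.85% in LPS cells, and 1.65%, 2.30% and 1.59% in calycosin plus LPS cells. Vehicle replicate 3 and calycosin plus LPS replicate 2 thus stood apart from their groups. The first principal component of log2 CPM carried 67.3% of the variance and the second 13.7%.

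**Figure D1:**
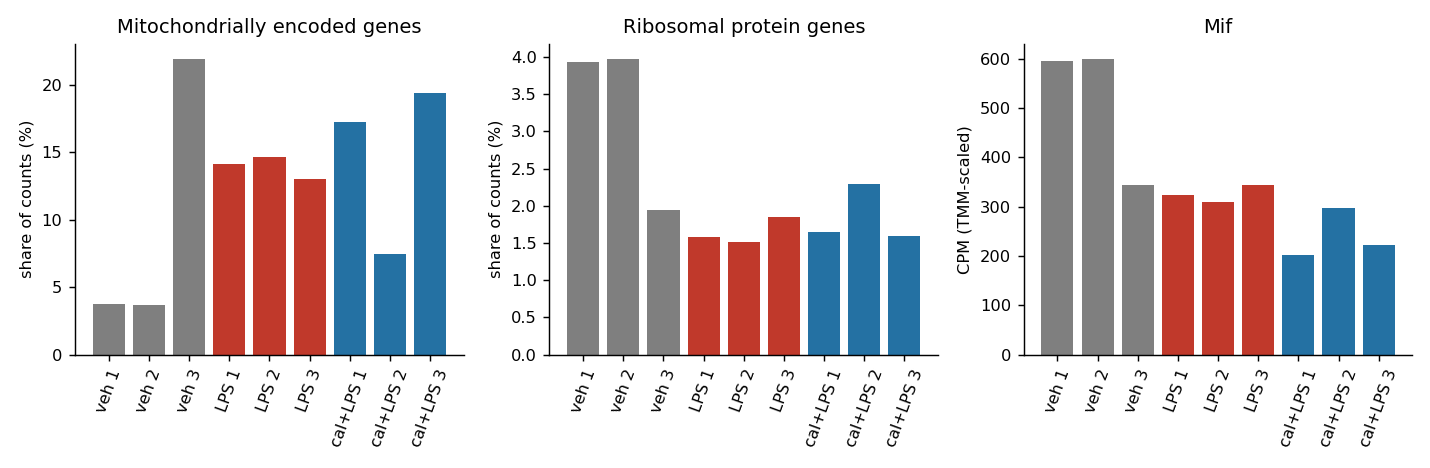
Composition of the 9 libraries: the panels plot, for each library of the vehicle, LPS and calycosin plus LPS groups, the percentage of counts from mitochondrially encoded genes, the percentage from cytosolic ribosomal protein genes, and the level of Mif in CPM, with a bar per library. The mitochondrial percentage was 3.79% and 3.68% in vehicle replicates 1 and 2 against 21.9% in replicate 3, and calycosin plus LPS replicate 2, at 7.45%, lay below the 17.2% and 19.4% of its group.

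The comparison of LPS with vehicle measured the inflammatory response on which calycosin was then tested. LPS turned on cytokine, chemokine and interferon-response genes that were silent or nearly silent in vehicle cells. Il6, an inflammatory cytokine, had no counts in any vehicle library and reached 355.5 ± 26.0 CPM, at least 5003-fold higher than a floor of 3 counts per library. Csf3, the granulocyte growth factor, rose from 0.0539 ± 0.0612 to 746 ± 42.3 CPM, and the antiviral protein gene Mx1 from 0.0137 ± 0.0237 to 251 ± 16.7 CPM, both from vehicle levels under that floor. Many genes of DNA replication, cell division and lipid synthesis fell over the same 6 h. With an estimated correlation in camera, the mitosis and cholesterol synthesis lists missed the threshold (adjusted p = 0.175 and 0.242). The stearoyl-CoA desaturase gene Scd2 fell 22.7-fold, from 529.8 ± 23.1 to 23.4 ± 2.88 CPM, and Cdc6, which loads the replicative helicase, fell 10.0-fold.

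At a Benjamini-Hochberg adjusted p below 0.05 in edgeR's quasi-likelihood test, 3954 genes were higher and 4180 lower with LPS. These were 27.3% and 28.9% of the genes tested, and 2361 and 2501 of them differed at least 2-fold. With limma on log2(TPM + 1) the counts were 1378 and 6681. Under the naming rule, which needs 10 CPM in the higher group, the largest fitted rises also included Slfn1, Ifi205, Iigp1 and Serpina3f, which had no counts in vehicle cells and were at least 3906-fold, 2391-fold, 2175-fold and 533.6-fold higher. Gbp5, a guanylate-binding protein of host defence, rose from 0.0644 ± 0.0256 to 891 ± 51.2 CPM. The largest fitted falls under the rule were in Tmem86a (from 13.5 ± 3.72 CPM to 0.055 ± 0.0477 CPM, under the floor), Kbtbd11 (214-fold, from 219 ± 56.9 to 1.02 ± 0.236 CPM), Ranbp3l (114-fold), the uracil-DNA glycosylase gene Ung (104-fold) and Chst1 (74.8-fold), followed by Klhl21 (67.8-fold), Rarb (48.5-fold) and Tfap4 (45.7-fold). The naming rule also required all 3 LPS libraries on the same side of all 3 vehicle libraries, which chance gives 10% of the time for a single gene. This separation was thus set by the selection and adds no support.

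Genes central to the study had these positions and values. Ccl2 (ENSMUSG00000035385, chromosome 11: 82035571 to 82037453), the monocyte chemoattractant, rose from 1.79 ± 0.412 to 1805.5 ± 396 CPM, a log2 fold change of 9.96 (SE 0.31, adjusted p = 1.06e-08). Tnf (ENSMUSG00000024401, chromosome 17: 35199381 to 35202007) rose from 26.4 ± 4.53 to 2905 ± 57.1 CPM, a log2 fold change of 6.78 (SE 0.24, adjusted p = 2.03e-08). Ptgs2 (ENSMUSG00000032487, chromosome 1: 150100031 to 150108227), the inducible cyclooxygenase, rose 451-fold to 3689.6 ± 340.1 CPM, and Nos2 (ENSMUSG00000020826, chromosome 11: 78920787 to 78960254), the inducible nitric oxide synthase, rose 266-fold to 3443 ± 351 CPM. Il1b (ENSMUSG00000027398, chromosome 2: 129364570 to 129371139) was without counts in vehicle cells and reached 35.2 ± 3.43 CPM, at least 495.9-fold higher. Il6 lies at chromosome 5: 30013114 to 30019981 (ENSMUSG00000025746). Hmox1 (ENSMUSG00000005413, chromosome 8: 75093621 to 75100589), which encodes heme oxygenase 1, fell 1.69-fold from 192.3 ± 17.6 to 113.5 ± 7.87 CPM (adjusted p = 0.00118). Cyp1b1 (ENSMUSG00000024087, chromosome 17: 79701537 to 79715061) had 0 counts in all 9 libraries, which allows up to 0.137 CPM in a library.

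Counts of list members are adjusted over all genes tested, and the counts adjusted over the list alone are given wherever they differ. Where 5 or fewer members of a list moved in a direction most are named, and names outside the fixed naming rule were chosen after their values were seen. All 15 chemokine genes tested and all 15 inflammatory cytokine genes tested rose with LPS (camera adjusted p = 6.47e-32 and 2.66e-45). Cxcl10 rose from 0.226 ± 0.13 to 2081 ± 114 CPM, Ccl7 from 0.0641 ± 0.0788 to 129 ± 17.1 CPM, Ccl5 3849-fold, and the interleukin gene Il1a 1712.5-fold. All 30 interferon-stimulated genes rose (adjusted p = 1.91e-96), among them Rsad2, which rose 4595-fold to 7453 ± 253 CPM. Of 22 genes of the NF-kappaB pathway and its feedback 21 rose, led by Nfkbiz (97.4-fold) and Traf1 (75.4-fold), and only the phosphatase gene Dusp2 fell (adjusted p = 2.90e-23). Of 21 genes of the TLR4 receptor and its signalling 13 rose and 2, the kinase genes Irak1 and Irak4, fell (adjusted p = 1.52e-06). Acod1, which makes itaconate, rose 701-fold to 5388 ± 58.4 CPM. Of 23 immediate early genes 16 rose, 18 adjusted over the list alone, led by Egr1 (243-fold) and Nr4a3, and Nr4a1 fell (adjusted p = 3.28e-09). All of these lists also passed the test with an estimated correlation.

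Receptors, enzymes and surface molecules of activated macrophages moved with them. Of 8 chemokine and chemoattractant receptors tested 7 rose, among them Ccrl2 (171-fold) and C5ar1 (70.7-fold), while the fractalkine receptor Cx3cr1 fell (adjusted p = 1.52e-06). Of 20 genes of macrophage migration and the cytoskeleton 15 rose, including the urokinase receptor Plaur (31.2-fold) and the protease Mmp9 (34.1-fold), and Vav1, Cd81 and Myo1f fell (adjusted p = 3.40e-05). Of 13 prostanoid and nitric oxide enzymes 8 rose, 9 adjusted over the list alone (adjusted p = 3.49e-05). The constitutive cyclooxygenase Ptgs1 and the leukotriene pathway genes Alox5 and Alox5ap fell. Of 18 antigen presentation genes 15 rose and none fell at an adjusted p below 0.05 in edgeR (adjusted p = 4.94e-11), with the costimulatory receptor Cd40 59.1-fold and the checkpoint ligand Cd274 36.2-fold higher. Of 13 inflammasome and pyroptosis genes 8 rose, 9 adjusted over the list alone, with Nlrp3 45.1-fold higher at 1277 ± 35.8 CPM, and the ATP receptor P2rx7 fell (adjusted p = 5.09e-05, and adjusted p = 0.0882 with an estimated correlation).

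Lists named for macrophage states and for other cell types were also tested. Of 12 genes of alternative activation 11 rose and the lectin gene Clec10a fell (adjusted p = 1.52e-06). The largest rises were in the growth regulator Myc (67.8-fold), the transglutaminase Tgm2 and Egr2, which LPS also raises in macrophages, and in the scavenger receptor Msr1. Of 18 macrophage identity genes 8 rose and 6 fell (adjusted p = 0.708), with the Fc receptor gene Fcgr1 5.54-fold higher and Cebpa, Trem2 and the growth factor receptor Csf1r 11.2-fold, 4.01-fold and 3.75-fold lower. Of 21 markers of other cell types only 3 had counts enough to be tested, all at low levels (list adjusted p = 0.631). The endothelial gene Cdh5 rose from 0.354 ± 0.205 to 4.76 ± 0.874 CPM and the dendritic cell gene Zbtb46 fell from 0.505 ± 0.0792 to 0.113 ± 0.0446 CPM. Pecam1 had 0.247 ± 0.0298 and 0.641 ± 0.236 CPM (adjusted p = 0.0687), so that 2 were higher and 1 lower adjusted over the list alone.

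Lists of proliferation and lipid synthesis genes were lower with LPS. Of 28 DNA replication genes 25 fell and none rose (adjusted p = 6.63e-15), with Gins2 and Ccne2 9.82-fold and 8.70-fold lower. Of 30 mitosis genes 24 fell, 25 adjusted over the list alone, led by Foxm1 (6.48-fold) and Aurkb (5.56-fold), and the kinesin gene Cenpe and the securin gene Pttg1 rose (adjusted p = 2.66e-06, and adjusted p = 0.175 with an estimated correlation). Of 16 fatty acid synthesis genes 10 fell, among them Elovl6 (7.93-fold) and Fasn (7.38-fold), and the acyl-CoA synthetase gene Acsl1 and the lipid droplet gene Plin2 rose (adjusted p = 1.19e-04). Of 24 cholesterol synthesis genes 11 fell, with Dhcr7 8.36-fold lower, and 1 rose (adjusted p = 0.00218, and adjusted p = 0.242 with an estimated correlation). Of 12 LXR-regulated cholesterol efflux genes 6 fell, including the transporter Abcg1 (2.48-fold), and Nr1h3, which encodes LXR alpha, rose (adjusted p = 0.0288, and adjusted p = 0.175 with an estimated correlation). The call of this list was lost with a correction for GC content (adjusted p = 0.0981) and with the mitochondrial share as a covariate (0.0688), in a range of 0.0140 to 0.0981 over the refitted models.

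Ribosomal protein and mitochondrially encoded genes were spread widely within the vehicle group. Of 26 cytosolic ribosomal proteins 8 fell and Rps6 rose, 6 and 1 adjusted over the list alone. The list adjusted p was 0.224, in a range of 4.1e-04 to 0.88 over the refitted models. Rps2 had 79.2 ± 40.9 CPM in vehicle and 30.5 ± 1.45 CPM in LPS cells. Of 31 oxidative phosphorylation genes 9 fell and Uqcrb and Cycs rose (adjusted p = 0.239), 7 and 2 adjusted over the list alone, with Sdhd 3.01-fold lower. The Uqcrb call was lost without vehicle replicate 1 or 2 or LPS replicate 3 (highest adjusted p = 0.0977). None of the 13 mitochondrially encoded mRNAs passed in edgeR, adjusted or not (list adjusted p = 0.509, in a range of 1.7e-11 to 0.85). Of these, DESeq2 called 1 higher and limma on TPM 1 higher and 1 lower. Among them mt-Co1 had 21113 ± 18395 CPM in vehicle and 46589 ± 1734 CPM in LPS cells. Of 16 glycolysis genes Slc2a1, Hk2 and Pfkp rose and Pfkl, Tpi1, Pkm, Ldha and the lactate transporter Slc16a1 fell (adjusted p = 0.570). Of 26 ribosome biogenesis genes 13 fell while Ddx21 and Myc rose (adjusted p = 0.175), 3 rising adjusted over the list alone.

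Mif (ENSMUSG00000033307, chromosome 10: 75859353 to 75860240), which encodes the macrophage migration inhibitory factor named in the study's title, had 512.5 ± 147 CPM in vehicle and 325.6 ± 16.7 CPM in LPS cells, a log2 fold change of -0.65 (SE 0.22, adjusted p = 0.0298). The groups overlapped, because vehicle replicate 3, the library with 21.9% mitochondrial counts, lay among the LPS libraries. The call was lost when vehicle replicate 1 or 2 or any 1 of the LPS libraries was left out (adjusted p = 0.0826, 0.0822, 0.0789, 0.0889 and 0.0609). The log2 fold changes in these fits were -0.58, -0.58, -0.64, -0.62 and -0.69. Among the libraries of high mitochondrial share the log2 fold change was -0.10 (adjusted p = 0.530). With the GC content offset the direction turned, to 0.12 (adjusted p = 0.483), and adjusted p ranged from 1.66e-05 to 0.530 over all alternatives. Cd74, which encodes the MIF receptor and invariant chain (ENSMUSG00000024610, chromosome 18: 60803848 to 60812652), rose from 410.2 ± 12.3 to 1018 ± 36.3 CPM. The Cd74 call was lost in the limma fits on TPM (log2 fold change 0.53 in both, adjusted p = 0.142 and 0.139, in a range of 2.08e-25 to 0.142). Of the 6 genes for MIF and its receptors tested, Cd74 and its co-receptor gene Cd44 (11.2-fold) rose, while Mif, its paralog Ddt and the receptor Cxcr4 fell (list adjusted p = 0.599). The median (-0.26) and mean (-0.44) log2 fold changes of the list were negative and its test pointed upward. The fall of Ddt, -0.82 in log2 fold change (adjusted p = 0.0481), also depended on the libraries used and was 0.02 among those of high mitochondrial share.

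The comparison of calycosin plus LPS with LPS asked what the pretreatment changed in the LPS response, which the study describes as an anti-inflammatory action. Among cytokine and chemokine genes, Il1b, Il1a, Csf3 and Ccl2 were lower with calycosin pretreatment. Il1b fell 101-fold, from 35.2 ± 3.43 to 0.334 ± 0.137 CPM, and Il1a fell 38.8-fold, from 178 ± 13.2 to 4.6 ± 0.677 CPM. Csf3 fell 21.7-fold to 34.3 ± 12 CPM and Ccl2 6.58-fold to 274.6 ± 43.5 CPM, whereas Cxcl10 stood at 2081 ± 114 and 2376 ± 172 CPM (adjusted p = 0.546). Many lipid synthesis and DNA replication genes were higher than with LPS alone, though the cholesterol synthesis list missed the threshold with an estimated correlation in camera (adjusted p = 0.0990). Scd2 rose 5.83-fold to 136 ± 10.1 CPM, Dhcr7 4.53-fold and Cdc6 3.44-fold. Il23a, a subunit of interleukin 23, rose 4.05-fold to 176.4 ± 15.5 CPM and the complement gene C3 3.76-fold to 174.4 ± 8.05 CPM.

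**Figure D2:**
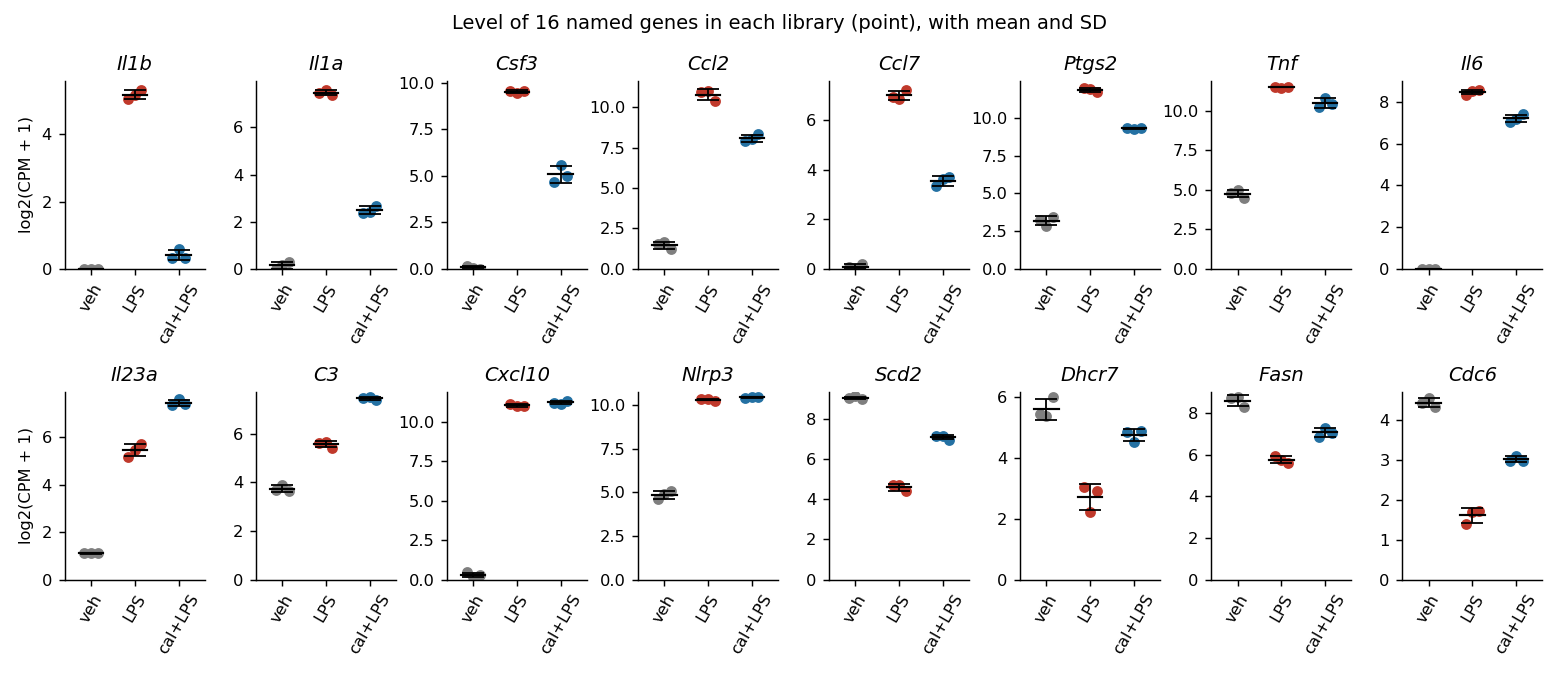
Levels of 16 genes in the 9 libraries: each panel plots log2(CPM + 1) for 1 gene in the vehicle, LPS and calycosin plus LPS groups, with a point per library, a line at the mean and a bar of 1 SD (n = 3). Il1b, Il1a, Csf3, Ccl2, Ccl7 and Ptgs2 rose with LPS and were lower with calycosin plus LPS, Il23a and C3 were higher again, Cxcl10 (2081 and 2376 CPM) and Nlrp3 (1277 and 1403 CPM) stood close together in both LPS groups, and Scd2, Dhcr7, Fasn and Cdc6 fell with LPS and were partly restored.

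By the same edgeR test 2333 genes were higher and 1871 lower with calycosin plus LPS than with LPS alone, which is 16.1% and 12.9% of the genes tested. Of these 1020 and 639 differed at least 2-fold. The count of lower genes was 1224 without calycosin plus LPS replicate 1, and with limma on log2(TPM + 1) the counts were 1334 and 281. Under the naming rule, which needs 10 CPM in the higher group, the largest falls were in Serpinb2, a plasminogen activator inhibitor (194-fold, from 24.1 ± 1.38 to 0.110 ± 0.118 CPM), Il1b, Il1a, the vasoconstrictor peptide gene Edn1 (38.2-fold), Csf3, Ccl7 (11.8-fold), Pilra (11.3-fold) and Csf2 (10.7-fold). The largest rises under the rule were in the metalloproteinase gene Mmp19 (8.03-fold, from 2.58 ± 0.534 to 20.7 ± 1.91 CPM), the aggrecanase gene Adamts4 (5.93-fold), the transcription factor gene Grhl1 (5.90-fold), Scd2, Zfp398 (5.55-fold) and Cdca7 (4.70-fold). Ifit1bl2 and the protocadherin gene Pcdhgb4, which the naming rule also took, share sequence with neighbouring paralogs, and the Pcdhgb4 call was lost without 5 of the single libraries (highest adjusted p = 0.0780). In simulated data with far fewer changed genes, 6% of genes changed 1.5-fold and 90% of genes changed 4-fold were called. These shares do not carry over to the real comparison, where most of the called genes differed less than 2-fold.

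Among the inflammatory cytokines 10 of 15 tested fell, 11 adjusted over the list alone, and 3 rose (adjusted p = 1.11e-13, and adjusted p = 0.0280 with an estimated correlation). Tnf fell from 2905 ± 57.1 to 1470.3 ± 317 CPM, a log2 fold change of -0.98 (SE 0.19, adjusted p = 0.00434). In the limma fits on TPM the Tnf call was lost (log2 fold change -0.67 in both, adjusted p = 0.257 and 0.254, in a range of 3.19e-06 to 0.257). Il6 fell from 355.5 ± 26.0 to 148.9 ± 19.2 CPM, a log2 fold change of -1.26 (SE 0.13, adjusted p = 6.07e-04). The genes that rose were Il23a, the macrophage growth factor Csf1 and the costimulatory ligand Tnfsf9, and the members that fell included the interleukin 1 receptor antagonist Il1rn, which dampens rather than drives inflammation. Among 15 chemokines 8 fell, with Ccl12, Ccl7 and Ccl5 15.4-fold, 11.8-fold and 4.09-fold lower, and Ccl22 and Cxcl11 rose. The list adjusted p was 7.44e-05 (adjusted p = 0.0663 with an estimated correlation), with 3 rising adjusted over the list alone. Among 8 chemoattractant receptors Ccr1 (3.33-fold), Cxcr3 (3.73-fold) and Ccrl2 fell and the nucleotide receptor P2ry6 rose, 5 falling adjusted over the list alone (adjusted p = 0.0189, and adjusted p = 0.0990 with an estimated correlation). Among 20 migration and cytoskeleton genes 12 fell, including Mmp9 (3.76-fold) and Plaur (2.71-fold), and Icam1 and Cd81 rose (adjusted p = 1.19e-06, and adjusted p = 0.0380 with an estimated correlation).

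Signalling and effector genes fell in part. Among 22 NF-kappaB genes 7 fell and Nfkbie rose, 8 and 2 adjusted over the list alone (adjusted p = 0.00271, and adjusted p = 0.0990 with an estimated correlation). The members that fell most, Socs3 (5.70-fold), Zc3h12a (2.63-fold) and Tnip1 (2.32-fold), are known as negative regulators of inflammatory signalling. Among 21 TLR4 pathway genes 8 fell, 9 adjusted over the list alone, with Cd14 2.47-fold and Myd88 2.11-fold lower, and the DNA sensor Tlr9 (4.12-fold) and Ticam2 rose (adjusted p = 0.0265, and adjusted p = 0.198 with an estimated correlation). Without LPS replicate 1 this list had an adjusted p of 0.0562, in a range of 0.00997 to 0.0562 over the refitted models. Among 30 interferon-stimulated genes 13 fell, 15 adjusted over the list alone, and Irf1 rose (adjusted p = 5.28e-05, and adjusted p = 0.0380 with an estimated correlation). Ifit2 fell 2.27-fold and Rsad2 2.03-fold, while Gbp5 had 891 ± 51.2 and 743 ± 18.1 CPM (adjusted p = 0.132). Among 13 prostanoid and nitric oxide enzymes 6 fell and Ptgs1 rose, 7 and 2 adjusted over the list alone (adjusted p = 0.00160, and adjusted p = 0.0920 with an estimated correlation). Ptgs2 fell 5.79-fold to 637 ± 11.2 CPM, and Nos2 fell 1.51-fold to 2278 ± 105 CPM (adjusted p = 0.0160). The Nos2 call was lost without LPS replicate 1 (0.0628), calycosin plus LPS replicate 1 (0.0661) or calycosin plus LPS replicate 3 (0.0529) and in the limma fits on TPM (0.550 and 0.565, log2 fold change -0.26 in both), in a range of 1.08e-04 to 0.565 over the alternatives. Among 23 immediate early genes 9 fell and Jund and Klf2 rose, 10 and 3 adjusted over the list alone (adjusted p = 1.95e-04, and adjusted p = 0.0455 with an estimated correlation), with Nr4a2 6.18-fold, Egr2 3.70-fold and Ier2 3.69-fold lower.

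Few inflammasome and antigen presentation genes were called. Of 13 inflammasome genes Casp1 (2.38-fold) and Gsdmd fell (adjusted p = 0.155), and Nlrp3 had 1277 ± 35.8 and 1403 ± 30.6 CPM (adjusted p = 0.502). The Gsdmd call was lost without 4 of the single libraries (highest adjusted p = 0.0695). Of 18 antigen presentation genes the costimulatory ligands Cd86 (2.70-fold) and Cd80 (2.15-fold) and the immunoproteasome gene Psmb8 fell and Cd83 rose 2.65-fold (adjusted p = 0.133). Of 18 macrophage identity genes 9 fell, 10 adjusted over the list alone, including Fcgr2b (2.77-fold) and Cd53 (2.64-fold), and Cebpa rose 2.51-fold (adjusted p = 7.96e-04, and adjusted p = 0.0990 with an estimated correlation). Of 12 alternative activation genes Mrc1, Clec7a, Egr2, Msr1 and Tgfb1 fell and Clec10a and Irf4 rose (adjusted p = 0.0130, and adjusted p = 0.0948 with an estimated correlation), 6 falling adjusted over the list alone. Of the 3 testable markers of other cell types Cdh5 fell 7.08-fold to 0.671 ± 0.0922 CPM and Zbtb46 rose from 0.113 ± 0.0446 CPM, under the floor, to 0.867 ± 0.181 CPM (list adjusted p = 0.4996).

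Lipid synthesis and replication genes moved upward together. Among 16 fatty acid synthesis genes 11 rose, 12 adjusted over the list alone, and Acsl1 fell (adjusted p = 1.19e-06, and adjusted p = 0.0455 with an estimated correlation). Dgat2 rose 4.69-fold, Scd1 3.52-fold and Fasn 2.53-fold, from 53.1 ± 6.17 to 134 ± 20.9 CPM. Among 24 cholesterol synthesis genes 12 rose and none fell, 15 rising adjusted over the list alone (adjusted p = 4.26e-06, and adjusted p = 0.0990 with an estimated correlation), with Stard4 3.17-fold and Idi1 2.42-fold higher. Among 12 LXR-regulated genes the cholesterol exporters Abca1 (1.87-fold) and Abcg1 (1.88-fold), Lpcat3, Scd1 and Scd2 rose and Smpdl3a fell, 6 rising adjusted over the list alone (adjusted p = 9.12e-04, and adjusted p = 0.0846 with an estimated correlation). Among 28 DNA replication genes 21 rose and none fell in edgeR (0 in DESeq2), 23 and 1 adjusted over the list alone (adjusted p = 3.08e-11, and adjusted p = 0.0239 with an estimated correlation), with Ung 8.02-fold and Ccne2 4.67-fold higher. Among 30 mitosis genes 11 rose and none fell (adjusted p = 0.0522), Birc5 1.89-fold and Aurkb 1.82-fold.

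Glycolysis genes went the other way from lipid synthesis. Of 16 tested 8 fell, 10 adjusted over the list alone, including the glucose transporter Slc2a1 (1.98-fold) and Pfkp (1.72-fold), and the lactate transporter Slc16a1 rose 2.28-fold (adjusted p = 0.00110, and adjusted p = 0.437 with an estimated correlation). Of 31 oxidative phosphorylation genes only Cycs fell (adjusted p = 0.0522). Of 26 ribosomal proteins Rpl30 and Rps18 fell, 0 adjusted over the list alone and 3 at an unadjusted p below 0.05 (adjusted p = 0.145). Of 26 ribosome biogenesis genes Polr1a and Nop56 rose and Rrs1, Ddx21 and Gnl3 fell, 1 and 3 adjusted over the list alone (adjusted p = 0.491). Without 4, 7, 4 and 3 of the single libraries the calls of Rpl30, Rps18, Nop56 and Gnl3 were lost (highest adjusted p = 0.0734, 0.147, 0.0860 and 0.0659). No mitochondrially encoded mRNA passed in the main edgeR fit, with or without adjustment, nor in DESeq2 or limma (list adjusted p = 0.491), with mt-Co1 at 46589 ± 16168 CPM in the calycosin plus LPS group, whose mitochondrial shares were 17.2%, 7.45% and 19.4%. Without both libraries that stand apart mt-Co1 was called higher (log2 fold change 0.29, adjusted p = 0.0308). Among libraries of high mitochondrial share its log2 fold change was 0.28.

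Mif had 325.6 ± 16.7 CPM with LPS and 240.1 ± 50.4 CPM with calycosin plus LPS, a log2 fold change of -0.44 (SE 0.22, adjusted p = 0.167). It passed the threshold in a fit of the 6 libraries compared (adjusted p = 0.0441), without vehicle replicate 3 (adjusted p = 0.0345) and among the libraries of high mitochondrial share (log2 fold change -0.60, adjusted p = 0.00327). It also passed with the GC content offset (-0.61, adjusted p = 0.00864), with the mitochondrial share as a covariate (-0.47, adjusted p = 4.81e-04) and without both libraries that stand apart (-0.60, adjusted p = 8.88e-04). Its adjusted p ranged from 4.81e-04 to 0.878 over the alternatives. Cd74 had 1018 ± 36.3 and 873.4 ± 105 CPM (adjusted p = 0.208). It was called lower among the libraries of high mitochondrial share (log2 fold change -0.30, adjusted p = 0.0263) and without both libraries that stand apart (-0.30, adjusted p = 0.00922), in a range of 0.00922 to 0.843. Of the 6 genes for MIF and its receptors only Cxcr4 rose, from 0.0547 ± 0.0947 to 0.430 ± 0.219 CPM, 0 adjusted over the list alone (list adjusted p = 0.644). The Cxcr4 call (adjusted p = 0.0335) was lost without LPS replicate 1 (0.0963) or 3 (0.0966) and without calycosin plus LPS replicate 1 (0.0955) or 2 (0.0755). It was also lost with the replicate block (0.0642), with limma on log2(TPM + 1) (0.157), among the libraries of high mitochondrial share (0.0866) and without both libraries that stand apart (0.0587), in a range of 0.00425 to 0.157. The median log2 fold change of the list was -0.25 and its mean 0.26. Hmox1 rose 1.56-fold, from 113.5 ± 7.87 to 177.2 ± 29.3 CPM (adjusted p = 0.00758), a log2 fold change of 0.64. In the limma fits on TPM the call was lost while the log2 fold changes were 0.95 and 0.96 (adjusted p = 0.0884 and 0.0839, in a range of 4.65e-04 to 0.0884).

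The calycosin difference was largely opposite in sign to the LPS response. Of 2361 genes that LPS raised at least 2-fold, 919 (38.9%) were lower with calycosin plus LPS than with LPS and 79 (3.35%) were higher. Of 2501 genes that LPS lowered at least 2-fold, 1133 (45.3%) were higher and 47 (1.88%) were lower. With limma on log2(TPM + 1) the counts of LPS-raised genes were 184 and 26 and those of LPS-lowered genes 821 and 5. Without vehicle replicate 3 the 79 became 132 and the 47 became 87. The 79 became 49, 52 and 50 without LPS replicate 1, LPS replicate 2 and calycosin plus LPS replicate 1. The 47 became 30 without vehicle replicate 1, 24, 25 and 29 without LPS replicates 1, 2 and 3, and 22 without calycosin plus LPS replicate 1 or 3. Among the LPS-raised genes the further rises were led by Adamts4 (from 7.75 ± 1.09 to 46.0 ± 7.83 CPM), Il23a and C3, and among the LPS-lowered genes the further falls included the transporter genes Slco4a1 (3.04-fold) and Atp9a (2.24-fold). A median of 75.9% (quartiles 56.5% to 93.6%) of the log2 change from vehicle was left among LPS-raised genes, and 59.1% (35.7% to 80.8%) among LPS-lowered genes. Both comparisons use the same LPS libraries, so part of the excess may come from chance values that they share. In 20 simulations without a calycosin effect a median of 0 LPS-raised genes fell (highest 1), 0 rose, and 0 LPS-lowered genes moved in either direction. Counts near 0 are expected where no effect is simulated, so they do not measure how far the shared libraries add to the opposite calls. Independent lists, which leave out the shared libraries, would share 305.5, 381, 403.6 and 323.7 genes. The log2 fold changes of all tested genes had a Pearson correlation of -0.54 across genes, which are not independent replicates, against -0.12 in the simulations (-0.15 to -0.10). They had a covariance of -0.88 against -0.09, a difference of -0.79.

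**Figure D3:**
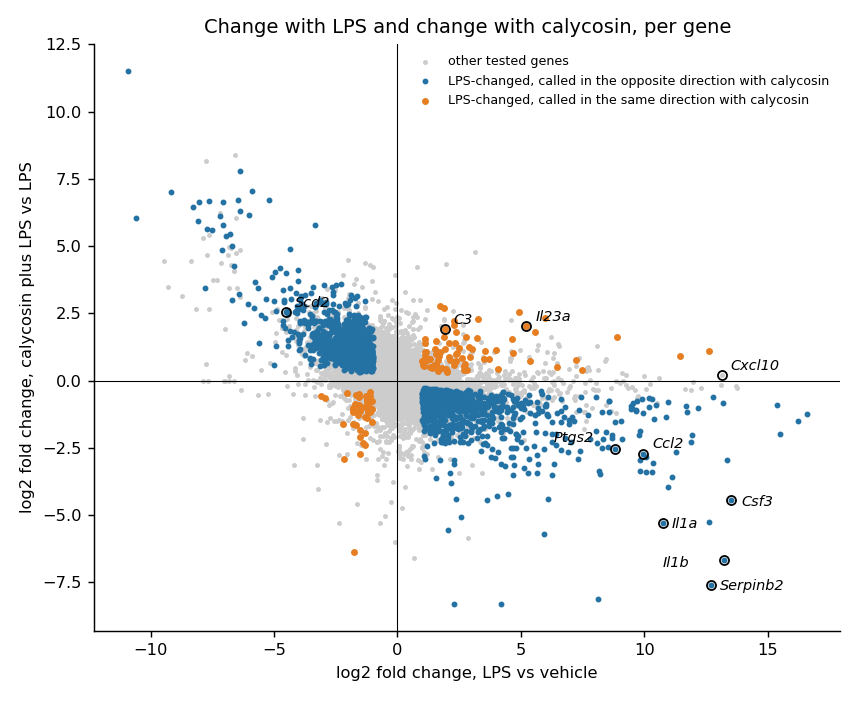
Calycosin change against LPS change for the 14458 genes tested: the x axis is the log2 fold change of LPS over vehicle and the y axis that of calycosin plus LPS over LPS, with 1 point per gene and colours for LPS-changed genes called in the opposite or in the same direction with calycosin. Of the genes LPS raised, 919 were called lower and 79 higher with calycosin, and of those it lowered, 1133 were called higher and 47 lower. Fitted fold changes of genes at 0 in a group depend on the small prior count that edgeR adds in its fit.

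The comparison of calycosin plus LPS with vehicle showed how far from resting cells the pretreated cells remained. Inflammatory genes were still above the vehicle level. Il6 was at least 2096-fold higher than in vehicle cells, Cxcl10 10272-fold, Ccl2 151-fold, Nos2 176-fold, Ptgs2 77.9-fold and Tnf 55.7-fold. Il1b, without counts in vehicle cells, was at least 4.70-fold higher, a call lost with limma on log2(TPM + 1) (log2 fold change 0.48, adjusted p = 0.0876, in a range of 1.52e-06 to 0.0876). Hmox1 had 192.3 ± 17.6 and 177.2 ± 29.3 CPM (adjusted p = 0.504), and was called lower without both libraries that stand apart (log2 fold change -0.36, adjusted p = 0.0145, in a range of 0.0145 to 0.993). In that fit the mitochondrial share also separated the vehicle libraries from the calycosin plus LPS libraries. Many proliferation genes stayed below the vehicle level, with Cdc6 2.91-fold and Aurkb 3.05-fold lower, and so did Scd2 (3.89-fold). The mitosis list, which holds Aurkb, missed the threshold with an estimated correlation in camera (adjusted p = 0.240). Against vehicle, 3672 genes were higher and 3413 lower (25.4% and 23.6% of genes tested), 1949 and 1721 of them at least 2-fold. With limma on log2(TPM + 1) 1373 were higher, and among the libraries of high mitochondrial share 1981 were lower. The largest fitted rises under the naming rule also included Slfn1, Iigp1 and Ifi205 (at least 1378-fold, 1157-fold and 609.3-fold) and Mx1 (from 0.0137 ± 0.0237 to 219.8 ± 13.8 CPM), and the largest falls Kbtbd11 (138-fold), Ranbp3l (102-fold), Klhl21 (33.1-fold) and Cnnm1 (21.6-fold).

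All 15 chemokines, all 15 inflammatory cytokines and all 30 interferon-stimulated genes were higher than in vehicle cells (adjusted p = 2.48e-35, 1.17e-43 and 9.60e-120), with Ccl22 at 0.0274 ± 0.0475 and 49.8 ± 2.49 CPM and Ccl5 940.3-fold higher. So were 21 of 22 NF-kappaB genes (adjusted p = 3.66e-25), 14 of 21 TLR4 pathway genes, where only the kinase gene Ikbkb was lower (adjusted p = 7.60e-06), and 15 of 23 immediate early genes, where Fosl2 and Nr4a2 were lower (adjusted p = 1.10e-06). Of 18 antigen presentation genes 16 were higher and H2-DMa lower (adjusted p = 1.46e-11), and 11 of 12 alternative activation genes were higher, again including Myc and Egr2 (adjusted p = 7.31e-06). Of 8 chemoattractant receptors Ccr1, Ccrl2, C3ar1, C5ar1 and P2ry6 were higher and Cx3cr1 lower (adjusted p = 1.19e-05). These 9 lists also passed with an estimated correlation. Of 13 prostanoid and nitric oxide enzymes 7 were higher and Ptgs1, Alox5 and Alox5ap lower, 7 and 4 adjusted over the list alone (adjusted p = 5.26e-04, and adjusted p = 0.0818 with an estimated correlation). Of 13 inflammasome genes 7 were higher and P2rx7 lower (adjusted p = 1.05e-04, and adjusted p = 0.111 with an estimated correlation). Of 20 migration genes 8 were higher, 9 adjusted over the list alone, with Icam1 10.1-fold higher, and Itgb2, Itga4, Vav1, Cd81 and Myo1f were lower (adjusted p = 0.0310, and adjusted p = 0.261 with an estimated correlation). The migration call was also lost in a fit of the 6 libraries compared (0.0532), with the mitochondrial share as a covariate (0.107) and without both libraries that stand apart (0.0606), in a range of 0.00428 to 0.107. Of 18 macrophage identity genes 7 were higher and 8 lower (adjusted p = 0.128), with a median log2 fold change of 0.00446, a mean of -0.31 and a list test that pointed downward. None of the 3 testable markers of other cell types passed in edgeR, DESeq2 or limma, and 1 was higher at an unadjusted p below 0.05 (list adjusted p = 0.714).

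Of 28 DNA replication genes 25 were lower and none higher (adjusted p = 3.38e-08, and adjusted p = 0.00750 with an estimated correlation). Of 30 mitosis genes 22 were lower and Cenpe and Pttg1 higher (adjusted p = 1.19e-05, and adjusted p = 0.240 with an estimated correlation). Of 16 fatty acid synthesis genes 8 were lower and Scd1, Dgat2 and Plin2 higher (adjusted p = 0.0939). Of 24 cholesterol synthesis genes 6 were higher and 7 lower, 6 and 8 adjusted over the list alone (adjusted p = 0.332). Of 12 LXR-regulated genes Abca1, Mylip, Lpcat3, Nr1h3 and Scd1 were higher and Abcg1, Apoe, Srebf1, Scd2 and Smpdl3a lower (adjusted p = 0.442). The Abca1 call was lost without vehicle replicate 1 (0.0512). Of 16 glycolysis genes 11 were lower and none higher, Ldha 2.90-fold (adjusted p = 0.00691, and adjusted p = 0.502 with an estimated correlation). Oxidative phosphorylation and ribosome lists were also lower. Of 31 oxidative phosphorylation genes 19 were lower and Cycs higher, 20 and 2 adjusted over the list alone (adjusted p = 0.00769, and adjusted p = 0.607 with an estimated correlation). Of 26 ribosomal proteins 16 were lower, 17 adjusted over the list alone (adjusted p = 0.0139, and adjusted p = 0.610 with an estimated correlation). Of 26 ribosome biogenesis genes 14 were lower and Myc higher (adjusted p = 0.0298, and adjusted p = 0.261 with an estimated correlation). Among the libraries of high mitochondrial share, of which 1 is a vehicle library, these 3 list calls were lost (adjusted p = 0.0989, 0.15 and 0.0548, the highest values over the refitted models, against lowest values of 5.05e-06, 1.39e-07 and 0.00960). No mitochondrially encoded mRNA passed in edgeR, adjusted or not (list adjusted p = 0.624, in a range of 4.5e-15 to 0.94). DESeq2 called 1 higher.

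Mif fell from 512.5 ± 147 CPM in vehicle to 240.1 ± 50.4 CPM in calycosin plus LPS cells, 2.13-fold, a log2 fold change of -1.09 (SE 0.22, adjusted p = 0.00299). All 3 calycosin plus LPS libraries lay below all 3 vehicle libraries, and the call held in every alternative run, with log2 fold changes from -1.53 to -0.49 and adjusted p from 4.02e-06 to 0.0237. Cd74 and Cd44 were 2.13-fold and 8.83-fold higher, and Ddt and Cxcr4 lower (list adjusted p = 0.713). The Cd74 call was lost in the limma fits on TPM (log2 fold change 0.64 and adjusted p = 0.112 in both, in a range of 5.36e-17 to 0.112). The median log2 fold change of the list was -0.51 and its mean -0.18, with a list test that pointed upward.

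**Figure D4:**
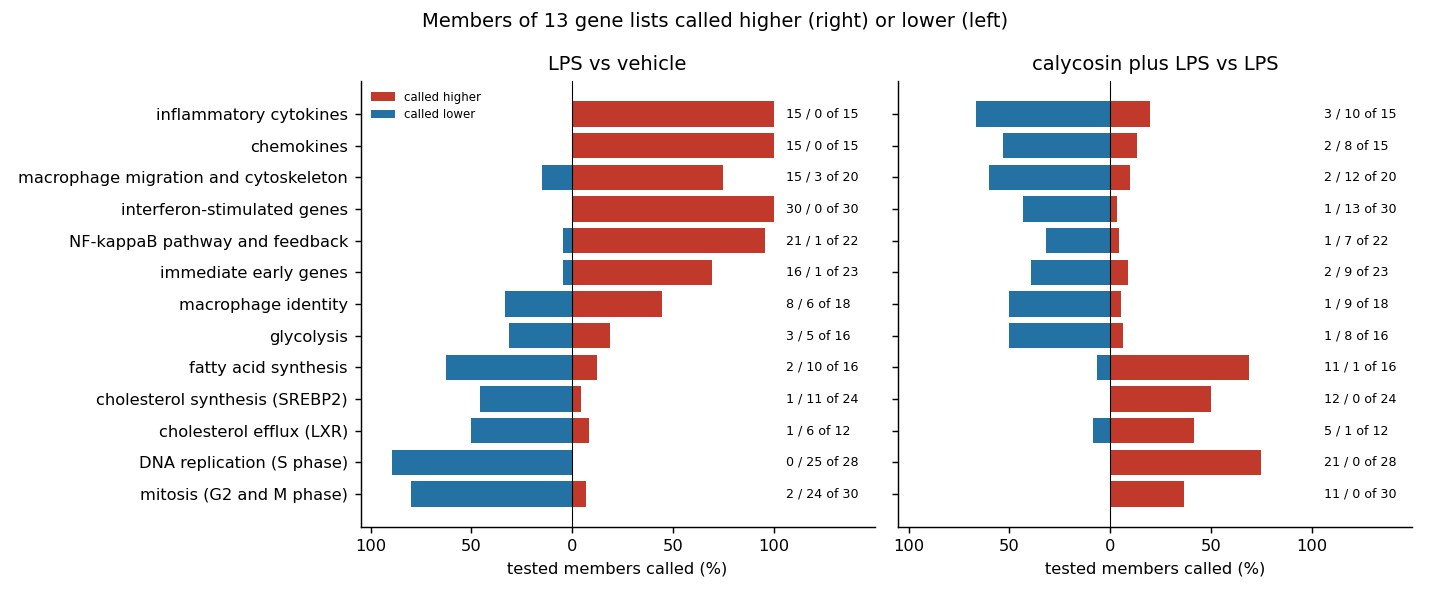
Share of list members called in 13 gene lists: bars to the right give the percentage of tested members called higher and bars to the left the percentage called lower, at an edgeR adjusted p below 0.05, for LPS against vehicle and for calycosin plus LPS against LPS. LPS raised all 15 cytokines, 15 chemokines and 30 interferon-stimulated genes, of which 10, 8 and 13 were lower with calycosin, and it lowered 25 of 28 DNA replication genes, a list in which 21 of the 28 were higher with calycosin.

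The balance of calls differed between the counts and the TPM values. In the counts 48.6%, 55.5% and 51.8% of called genes were higher in the comparisons of LPS with vehicle, calycosin plus LPS with LPS, and calycosin plus LPS with vehicle, and 50%, 49.6% and 49.8% with RLE size factors. In the deposited TPM values, tested with limma on another set of genes, these shares were 17.1%, 82.6% and 28.0%, and the log2 fold change of a gene differed from that in the counts by a median of -0.71, 0.30 and -0.41. The median log2 fold changes of all genes in the counts were -0.07, 0.02 and -0.005. TPM values are scaled to the same sum in each library and carry no correction for composition, so a change of small size is stated here relative to the median gene of the count data.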

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

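The fits with libraries of high mitochondrial share only, a GC content offset, the mitochondrial share as a covariate, mitochondrial genes and pseudogenes left out, or both libraries that stand apart left out were chosen after the data were seen, and the other alternatives were planned. No count of genes moved by more than 1.5 times with RLE size factors, the stricter filter, DESeq2, fits of the 6 libraries compared, the GC content offset or the counts without mitochondrial genes and pseudogenes. In DESeq2 98.8%, 98.9% and 97.9% of the genes called in LPS against vehicle, calycosin plus LPS against LPS and calycosin plus LPS against vehicle were called in the same direction. With the GC content offset these shares were 84.3%, 96.0% and 82.3%, and among the libraries of high mitochondrial share 67.2%, 88.6% and 58.5%, where 1 vehicle library leaves fewer degrees of freedom. The cause of the following changes was not tested, except that a stricter threshold lowers a count by construction. With limma on log2(TPM + 1) the log2 fold changes differed from those in the counts by medians of -0.71, 0.30 and -0.41. These shifts have the direction of the TMM factors: 1.05 to 1.42 in vehicle, 0.786 to 0.813 in LPS and 0.896 to 1.11 in calycosin plus LPS. The TPM values lack this scaling, so part of the changes in the TPM fits is a difference of scale. Without a filter 31 LPS-lowered genes were lower with calycosin. With limma on log2(TPM + 1), 1378 genes were higher and 6681 lower with LPS, 1334 higher and 281 lower with calycosin plus LPS against LPS, and 1373 higher against vehicle. In that fit 184 LPS-raised genes were lower and 26 higher with calycosin, and 5 LPS-lowered genes were lower. With log2(TPM + 0.1) the corresponding counts were 1384 and 6614, 290 lower against LPS, 1357 higher against vehicle, and 181, 32 and 12. With libraries of high mitochondrial share only, 1981 genes were lower in calycosin plus LPS against vehicle. With the covariate 3282 genes were lower in calycosin plus LPS against LPS and 124 LPS-raised genes were higher. Without both libraries that stand apart 166 LPS-raised genes were higher and 153 LPS-lowered genes lower with calycosin. At an adjusted p below 0.01, 1255 genes were higher and 965 lower in calycosin plus LPS against LPS and 2155 lower against vehicle. At that threshold 549 LPS-raised genes were lower and 39 higher with calycosin, and 687 LPS-lowered genes were higher and 18 lower. With a fold of at least 2 as well, the counts higher and lower were 2361 and 2501 for LPS, 1020 and 639 for calycosin plus LPS against LPS, and 1949 and 1721 against vehicle. At that fold 412 LPS-raised genes were lower and 34 higher, and 683 LPS-lowered genes were higher and 24 lower.

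Leaving out each library in turn gave 3253 to 4451 genes higher and 3605 to 5090 lower with LPS, 1697 to 3164 higher and 1224 to 2576 lower with calycosin plus LPS against LPS, and 2851 to 4376 higher and 2523 to 4337 lower against vehicle. All 6 highest counts came without vehicle replicate 3, and the lowest of 1224 without calycosin plus LPS replicate 1. LPS-raised genes lower with calycosin numbered 680 to 1215 and LPS-lowered genes higher with calycosin 897 to 1453. LPS-raised genes higher with calycosin numbered 49 to 132 and LPS-lowered genes lower with calycosin 22 to 87, both highest without vehicle replicate 3. The other counts that moved are given by library in the Results. Of 449 results for named genes 438 were called in the main fit. Without at least 1 library 36 of these lost the call, and 0 results changed sign. In the limma fits on TPM with the larger and the smaller addend 85 and 79 lost it, Tnf in calycosin plus LPS against LPS among them, as did 32 among libraries of high mitochondrial share and 11 with the GC content offset. Among genes named for LPS against vehicle, the highest adjusted p was 0.138 for Ddt (without vehicle replicate 2) and 0.0977 for Uqcrb (without LPS replicate 3). For calycosin plus LPS against LPS, it was 0.0966 for Cxcr4, 0.0780 for Pcdhgb4, 0.0860 for Nop56, 0.0734 for Rpl30 and 0.147 for Rps18 without a single LPS library. It was 0.0695 for Gsdmd, 0.0659 for Gnl3, 0.0785 for Fth1 and 0.127 for Itgb3 without a single calycosin plus LPS library, and 0.0512 for Abca1 against vehicle without vehicle replicate 1.

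Some log2 fold changes reversed in sign, where a change between values that both missed the threshold is not counted. In LPS against vehicle Mif was 0.12 with the GC content offset, Ddt 0.0205 and Rpl13 0.0409 with libraries of high mitochondrial share only, and Arnt -0.072 and -0.074 in the limma fits with the larger and the smaller addend. In calycosin plus LPS against LPS mt-Co1 was 0.28 with libraries of high mitochondrial share only and 0.29 without both libraries that stand apart. The cause was not tested. Of 111 list results 57 were called in the main fit, and 27 of these calls were lost with an estimated correlation. With the mitochondrial share as a covariate 3 calls were lost and 10 gained. Without both libraries that stand apart 4 were lost and 11 gained. The replicate numbers were also used as a replicate block. Deviations of libraries of the same number had correlations from -0.17 to 0.36, with -0.04, -0.10 and -0.14 between vehicle and LPS. Those of different numbers had correlations from -0.47 to 0.36. Both libraries that stand apart weigh on these values, so the check cannot tell whether the numbers pair the cultures. With the block, 3910 genes were higher and 3930 lower with LPS, 2113 and 1701 with calycosin plus LPS against LPS, and 3604 and 3163 against vehicle. Named genes whose call changed with the block were Cxcr4 (adjusted p = 0.0642) and Ugt1a6a (0.0509) in calycosin plus LPS against LPS, which lost it, and mt-Co1, which passed against vehicle with LPS (0.0309) and with calycosin plus LPS (0.0442). The oxidative phosphorylation and mitosis lists passed in calycosin plus LPS against LPS (0.0442 and 0.0406), and no other call of a named gene or list changed with the block. In simulated data of this depth and number of libraries, but with far fewer changed genes, changes near 1.5-fold were seldom called. That result does not carry over to the real comparisons.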

Other observations

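Several tests here were chosen after the result was seen: the test of GC content, the test of swapped libraries, the tests of Mif among libraries of high mitochondrial share, with the mitochondrial share as a covariate and with the GC content offset, and the medians of the SRF, ERK, cytokine and migration lists and of LPS-raised genes under those fits. The SRF and ERK lists were written after the fixed lists had been seen, and the other tests were set before their results were seen. Stress and survival genes moved in opposite directions within most lists after LPS. Of 23 apoptosis regulators 13 rose, with the survival genes Bcl2a1a and Cflar 4.41 and 2.76 higher on the log2 scale, and 6 fell, led by the death-promoting Bmf, which fell 30.6-fold (adjusted p = 0.00218, and adjusted p = 0.0573 with an estimated correlation). Of 28 ATF4 target genes 18 rose, among them Atf3 (15.6-fold), and Ddit4, Shmt2, Stc2 and Pck2 fell, 18 and 5 adjusted over the list alone (adjusted p = 0.00932, and adjusted p = 0.406 with an estimated correlation). This list had an adjusted p of 0.0887 without both libraries that stand apart, in a range of 2.10e-04 to 0.0887. Of 9 metallothionein and zinc genes 6 rose, with Mt2 5.72-fold higher, and Slc30a5 fell (adjusted p = 0.0479, and adjusted p = 0.138 with an estimated correlation). The metallothionein call was also lost without vehicle replicate 1 (0.0598), vehicle replicate 2 (0.0567) or LPS replicate 3 (0.0548) and in a fit of the 6 libraries compared (0.0600). It was lost as well among libraries of high mitochondrial share (0.0576), with the GC content offset (0.0981) and without both libraries that stand apart (0.0521), in a range of 0.0171 to 0.0981. Of 20 p53 targets 6 rose and 8 fell, 7 and 8 adjusted over the list alone (adjusted p = 0.352), with Fas and Plk2 51.9-fold and 37.3-fold higher and Phlda3 and Sesn1 17.7-fold and 14.3-fold lower. Of 20 hypoxia targets Hif1a, P4ha1, Slc2a1, Ero1l and Hilpda rose and 12 fell (adjusted p = 0.0987), with the oxygen sensor gene Egln3 6.88-fold lower. Of 29 lysosome and autophagy genes 10 rose and 8 fell (adjusted p = 0.708), including the regulator Tfeb, which fell 9.29-fold, and its relative Mitf, which rose 4.37-fold. Of 24 NRF2 genes Txnrd1, Slc7a11, Prdx1, Fth1 and Abcc1 rose and 10 fell (adjusted p = 0.224). Of 24 endoplasmic reticulum chaperone genes Hspa5, Hsp90b1, Herpud1, Syvn1 and Ssr3 rose and Pdia4, Sdf2l1, Hyou1 and Sec61b fell (adjusted p = 0.708), with Hspa5 3.82-fold higher. Of 14 heat shock genes Hsp90aa1, Hsp90ab1, Dnaja1 and Chordc1 rose and Hspa1a, Hspa1b, Hsph1 and Ahsa1 fell (adjusted p = 0.708). Of 13 iron genes Lcn2, which binds bacterial iron carriers, rose 28.0-fold with Slc11a2, Fth1, Ireb2 and Slc39a14, and 6 fell, among them the iron exporter Slc40a1 (adjusted p = 0.886). Of 12 osteoclast markers Mmp9, Src, Itgb3 and Dcstamp rose and Nfatc1, Tnfrsf11a and Car2 fell (adjusted p = 0.514). Of 6 aryl hydrocarbon receptor targets Tiparp and Arnt rose and Ahrr and Ugt1a6b fell (adjusted p = 0.966).

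With calycosin plus LPS against LPS, 10 of 28 ATF4 targets fell and Ddit3 and Nupr1 rose (adjusted p = 0.0130, and adjusted p = 0.419 with an estimated correlation). Of 20 p53 targets 7 rose and 7 fell, 9 and 7 adjusted over the list alone (adjusted p = 0.808), with Trp53inp1, Phlda3 and Sesn1 6.65-fold, 5.88-fold and 3.28-fold higher and Plk2 and Fas 5.61-fold and 2.32-fold lower, each opposite to its LPS change. Of 29 lysosome and autophagy genes Tfeb (3.06-fold), Ulk1, Wipi1, Neu1 and Mcoln1 rose and 9 fell, 5 and 12 adjusted over the list alone (adjusted p = 0.145). Of 24 endoplasmic reticulum chaperone genes 7 rose, among them Manf (1.79-fold), and Herpud1 fell (adjusted p = 0.145). Of 23 apoptosis regulators Bmf, Bcl2 and Pmaip1 rose and 4 fell, among them Mcl1, Bid and Casp8 (adjusted p = 0.808). Of 24 NRF2 genes Srxn1 (2.25-fold), Hmox1, Gclc and Slc48a1 rose and Slc7a11, G6pdx, Gsr, Gstm1 and Fth1 fell (adjusted p = 0.808). Of 20 hypoxia targets Adm, Ndrg1, Car9, Mxi1 and Pfkfb4 rose and Bnip3, P4ha1, Slc2a1, Pdk1 and Hilpda fell, 5 and 6 adjusted over the list alone (adjusted p = 0.670). Of 14 heat shock genes Hspa1a, Hspa1b and Hsph1 rose and Hspa8 fell (adjusted p = 0.741). Of 13 iron genes Slc40a1, Hmox1 and Steap3 rose and Fth1 fell (adjusted p = 0.543). Of 9 metallothionein and zinc genes Mt1, Mt2, Slc30a4 and Slc30a7 fell and Slc30a1 rose, 5 and 2 adjusted over the list alone (adjusted p = 0.222). Of 12 osteoclast markers Tnfrsf11a rose and Mmp9 and Itgb3 fell (adjusted p = 0.428), and of 6 aryl hydrocarbon receptor targets Ahrr and Ugt1a6a rose, 3 adjusted over the list alone (adjusted p = 0.203). The calls of Ahrr, Ugt1a6a, Car9, Pfkfb4, Hspa1a, Hsph1, Fth1 and Itgb3 were lost without some single libraries (highest adjusted p = 0.0527, 0.0963, 0.107, 0.116, 0.0779, 0.0884, 0.0785 and 0.127). Against vehicle, 12 of 23 apoptosis regulators were higher and Bax, Bbc3, Bmf and Casp9 lower in calycosin plus LPS cells (adjusted p = 5.03e-04, and adjusted p = 0.0340 with an estimated correlation). Of 20 hypoxia targets P4ha1, Hif1a and Hilpda were higher and 9 lower, 3 and 10 adjusted over the list alone (adjusted p = 0.0198, and adjusted p = 0.240 with an estimated correlation). This hypoxia call was lost with the covariate (0.0605) and without both libraries that stand apart (0.0537), in a range of 0.0173 to 0.0605. The other stress lists did not pass against vehicle. Of the NRF2 genes Txnrd1, Prdx1 and Abcc1 were higher and 10 lower, 11 adjusted over the list alone (adjusted p = 0.0968), and 6 metallothionein and zinc genes were higher, 7 adjusted over the list alone (adjusted p = 0.101). Of the ATF4 targets 12 were higher and 6 lower, 14 and 6 adjusted over the list alone (adjusted p = 0.137), and of the chaperones 13 were higher and Sdf2l1, Edem1 and Sec61b lower, 14 and 3 adjusted over the list alone (adjusted p = 0.165). Of the lysosome genes Ctsl, Npc1, Sqstm1 and Mitf were higher and 10 lower (adjusted p = 0.165), and of the p53 targets 8 were higher and 7 lower (adjusted p = 0.197). Tiparp and Arnt were higher and Ahrr lower (adjusted p = 0.485), and of the heat shock genes Hsp90aa1 was higher and Hsph1, Dnajb1, Hspa8, Ahsa1 and Hsf1 lower (adjusted p = 0.521). Of the osteoclast markers Atp6v0d2, Mmp9 and Src were higher and Ctsk, Nfatc1 and Car2 lower (adjusted p = 0.589). Of the iron genes Slc11a2, Ireb2, Lcn2 and Slc39a14 were higher and Slc40a1, Steap3, Aco1 and Ncoa4 lower (adjusted p = 0.624). Without some single vehicle or calycosin plus LPS libraries the calls of Sec61b, Ahrr, Dnajb1, Ahsa1 and Atp6v0d2 were lost (highest adjusted p = 0.0800, 0.0827, 0.0936, 0.0650 and 0.0612). The median, the mean and the test differed in sign for the lysosome, aryl hydrocarbon receptor, p53 and iron lists with LPS. They also did for the NRF2, p53, hypoxia and apoptosis lists with calycosin plus LPS against LPS, and for the iron list against vehicle.

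For the counts of genes called, the 10 splits of 6 libraries are too few for a share under 0.05. In LPS against vehicle 1 of the 10 splits gave as many genes, the real one with 8134, and the highest other gave 0. In calycosin plus LPS against LPS it was also 1 of the 10 (4204, highest other 1), and so it was against vehicle (7085, highest other 91). For LPS-raised genes lower with calycosin it was 1 of the 10 (919, highest other 0) and for LPS-lowered genes higher with calycosin 1 of the 10 (1133, highest other 1).

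Vehicle replicate 3 and calycosin plus LPS replicate 2 stood apart from their groups in opposite directions, with a correlation of -0.59 between their deviations across 11055 genes, which are not independent replicates. The deviation of vehicle replicate 3 had a Spearman correlation of -0.42 with GC content and that of calycosin plus LPS replicate 2 one of 0.48, so a GC-dependent difference between libraries may account for part of it. A swap of these libraries between groups is argued against by the LPS-raised genes, which in vehicle replicate 3 had a median log2 difference of 0.21 from the other vehicle libraries, where a swap needs at least 1. A different strength of the LPS response in calycosin plus LPS replicate 2 is argued against by a median log2 difference of -0.088 over the same genes. Whether the trend arose in the cultures, the RNA or the library preparation stays open, and transcript length followed it as well (0.255 and -0.225).

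Mif was lower in all 3 calycosin plus LPS libraries than in all 3 vehicle and all 3 LPS libraries, but overlapped between LPS and vehicle. In calycosin plus LPS against LPS its log2 fold change was -0.44 (adjusted p = 0.167, in a range of 4.81e-04 to 0.878 over the alternatives). There it was -0.61 with the GC content offset (adjusted p = 0.00864) and -0.47 with the mitochondrial share as a covariate (adjusted p = 4.81e-04). In LPS against vehicle its log2 fold change was -0.10 among libraries of high mitochondrial share, so the composition of the libraries may account for much of that difference. With the mitochondrial share as a covariate the log2 fold change was -0.27 (adjusted p = 0.0117, in a range of 1.66e-05 to 0.530 over the alternatives), while with the GC content offset it was 0.12 (adjusted p = 0.483). These fits disagree on whether LPS lowered Mif beyond the composition of the libraries. Against this composition as the whole cause in calycosin plus LPS against vehicle stands a log2 fold change of -0.70 among libraries of high mitochondrial share, which hold 1 vehicle library. It was -0.49 with the GC content offset (adjusted p = 0.0161) and -0.74 with the covariate (adjusted p = 3.77e-05). How much of the fall with LPS belongs to LPS stays open, and MIF protein was not analysed here.

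The genes that fell with calycosin included migration and cytokine genes, and lists of targets of the actin-regulated factors SRF and MRTF and of ERK signalling were tested for a shared fall. Of 30 SRF and MRTF targets 27 were tested and 17 were lower in calycosin plus LPS against LPS, including Actb, Actg1, Flna and Myh9, with a median log2 fold change of -0.71 (camera p = 5.01e-09, and p = 5.98e-04 with an estimated correlation). The median was -0.68 among libraries of high mitochondrial share and -0.77 with the GC content offset, so lower output of SRF and MRTF may be part of the calycosin effect, while Srf itself had a log2 fold change of -0.11 and did not pass. For ERK output, 7 of 16 genes tested were lower and Etv5 and Epha2 higher (median -0.44, camera p = 0.0632, and p = 0.0958 with an estimated correlation). A lower ERK output and no shift thus cannot be told apart. Of the 18 genes listed for ERK output, tested or not, 6 are also on the immediate early list. The LPS-raised genes called lower with calycosin had a median log2 fold change of -0.93, and the tables argue against GC content and mitochondrial share as the whole cause. Their median was -0.90 among libraries of high mitochondrial share, -0.97 with the GC content offset and -0.93 with the covariate, and 93.0%, 99.0% and 100% of the 919 genes were still called lower. These genes were picked for their fall, so the shares still called were nearly fixed in advance and add little. Over all genes in this comparison the offset and the covariate moved the log2 fold changes by medians of only 0.0430 and 0.00673. The members of the cytokine and migration lists were fixed beforehand, but these lists were picked for this check after their falls were seen. They pointed the same way. Their medians were -1.24 and -0.577 with the GC content offset, against -1.26 and -0.535 in all libraries. With the covariate they were -1.25 and -0.531, and among libraries of high mitochondrial share -1.22 and -0.489, with list adjusted p of at most 1.72e-06 in these fits. Other differences between the cultures or library preparations stay open, and an effect of calycosin without LPS stays untested.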
